A study of Arabidopsis thaliana with 208 samples.

How the data were processed

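The series, titled for the transcriptional regulation of nitrogen metabolism in Arabidopsis, measured gene expression in roots of seedlings 9 days old, grown on media with 1 or 10 mM KNO3. The wild type Col and 12 T-DNA insertion lines were used. Per the labels' protocols, seedlings of 2 plates were combined for a biological replicate and libraries were made by the BRAD-seq DGE method, which reads tags near the 3′ ends of transcripts. The labels give 4 replicates for each of the 26 groups. The KCl in the media was the same at both KNO3 concentrations, so potassium changed together with nitrate. Each library was sequenced in 2 runs, which gives 208 deposited samples.

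The deposited values are a whole-number read count per gene, 1 file per library and run, with totals that differ between files, and no normalization was found in them. Per the submitters' processing notes FastQC, Bowtie, SAMtools, HTSeq and limma were used with the build TAIR10, and the notes give no versions, roles or strand setting. Overlapping and antisense genes and genes with near-identical copies are therefore uncertain. Some are named as such in the comparison over all lines, and the limit holds wherever they are printed. The files list 33602 loci. Names were taken by locus tag from an annotation of assembly TAIR10.1, which matched 32835 of them and was used for names and for the order of neighbouring genes. The 279 organelle loci were left out because run 2 lists them all at 0, which leaves 33323 nuclear loci.

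Run 1 held between 801440 and 5981270 counts per library and run 2 between 2480098 and 8604318. Both were summed per library, for totals between 3981966 and 13695037. Libraries of the same group were checked for copies: between 156 such pairs the chi-square per degree of freedom was 6.66 or more (median 16.4), so none were exact copies. Between the runs of a library it was 5.25 or more (median 15.9), so the runs differ by more than counting error, and this measure cannot tell repeats of a library from separate libraries. Tags are counted without molecular identifiers in the files, so their number overstates the independent molecules. In 2 libraries, 10 mM replicate 3 of SALK_085964C and of SALK_035980, the names given to the files carry the other line. The labels were followed, and the alternatives exchange the pair or leave it out. All columns could be mapped to a group.

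Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group with a minimum count of 10, TMM factors, a quasi-likelihood fit with 1 coefficient for each of 26 groups, and Benjamini-Hochberg adjustment over the 19664 genes tested, with a threshold of 0.05. A gene past it is said to be called. The comparisons were nitrate in Col, nitrate over all lines, each of 12 lines against Col averaged over the concentrations, and for each line the difference between its nitrate response and that of Col. CPM values use the TMM factors and are given as mean ± SD over libraries. Log2 changes are those of the fit with their standard errors. The comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined, except that organelle loci were left out once their counts were seen.

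The rule names, among genes past the threshold and with at least 5 CPM in the higher group, the 12 with the largest rise and fall over all lines that have the same sign in all 13 lines, the 10 in Col, the 3 in each line with the same sign at both concentrations, and the 2 with the smallest adjusted p for each difference in response. It also names the gene lowest in each line against the other 12, and of each list the 4 members with the largest change. Genes outside the rule are said to be chosen after their values were seen.

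The 23 lists, written from general knowledge, cover high-affinity nitrogen uptake, nitrate reduction, ammonium assimilation, nitrate-responsive regulators, cytokinin, auxin, jasmonate and abscisic acid response, indole and aliphatic glucosinolates, flavonoids, low oxygen response, sulfate and phosphate starvation, iron deficiency, and markers of photosynthetic tissue, root hair, xylem, phloem, endodermis, root cap, dividing cells and seed. They hold 288 members, all of which the files list. Lists with at least 3 tested members were tested by camera (limma 3.58.1) on voom values, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, or over lists and lines for the line effects. Estimated correlations and fry were alternatives.

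Each step was tested on simulated data: counts drawn from the means and library sizes of the real genes, with 50 genes changed at each of 4 sizes. The changed genes had a mean of at least 5 CPM. The spread was that of the trend over genes and no strip effect was drawn, so the shares called may be too high for the genes tested. For nitrate in Col (19414 genes) edgeR called 2% of genes changed 1.25-fold, 36% at 1.5-fold, 86% at 2-fold and 100% at 4-fold, with 6 false calls. Over all lines (19417 genes) it called 100% at each size, with 7 false calls. For the line effect of SALK_012253 (19415 genes) it called 10%, 92%, 100% and 100%, with 5 false calls, and for its difference in response (19420 genes) 0%, 8%, 62% and 100%, with 6 false calls. Camera called the changed list and 0 of 20 unchanged lists in each of these cases. The genes were drawn independently of each other, so this cannot show how often camera calls a list of unchanged but correlated genes.

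The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, RLE factors in place of TMM, no low-count filter, a fit to the compared groups alone, run 1 or run 2 alone, organelle genes kept, replicate number as a block term, strip as a covariate, the 3 strips with both concentrations, other insertion lines in place of Col, GABI_699B09 left out, and each replicate number or Col library left out in turn. Other splits of the libraries were tested with limma-trend.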

Results

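Transcripts were counted by 3′ tag sequencing in roots of 9-day-old Arabidopsis seedlings grown on 1 or 10 mM KNO3. The plants were the wild type Col and 12 lines that each carry a T-DNA insertion, a piece of bacterial DNA placed in the genome: GABI_513E07, GABI_699B09, GABI_868_E02, SAIL_1207_H04, SALK_012253, SALK_015182, SALK_035980, SALK_070847C, SALK_085964C, SALK_094437C, SALK_100002 and SALK_146141. Each of the 26 combinations of line and concentration had 4 biological replicates, and each library was sequenced in 2 runs. With both runs summed, a library held between 3981966 and 13695037 counts, with a median of 8.33e+06, and between 20724 and 22094 genes had a count. Libraries separated first by KNO3 concentration and then into GABI_699B09 and the rest: the first principal component held 38.4% of the variance, of which 97.3% lay between the concentrations, while the second held 6.53%, of which 90.4% lay between the lines, with GABI_699B09 apart from the other lines, which intermixed. The libraries were prepared in 13 strips of 8, and 5 strips held 1 mM libraries alone, 5 held 10 mM libraries alone and 3 held both.

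**Figure D1:**
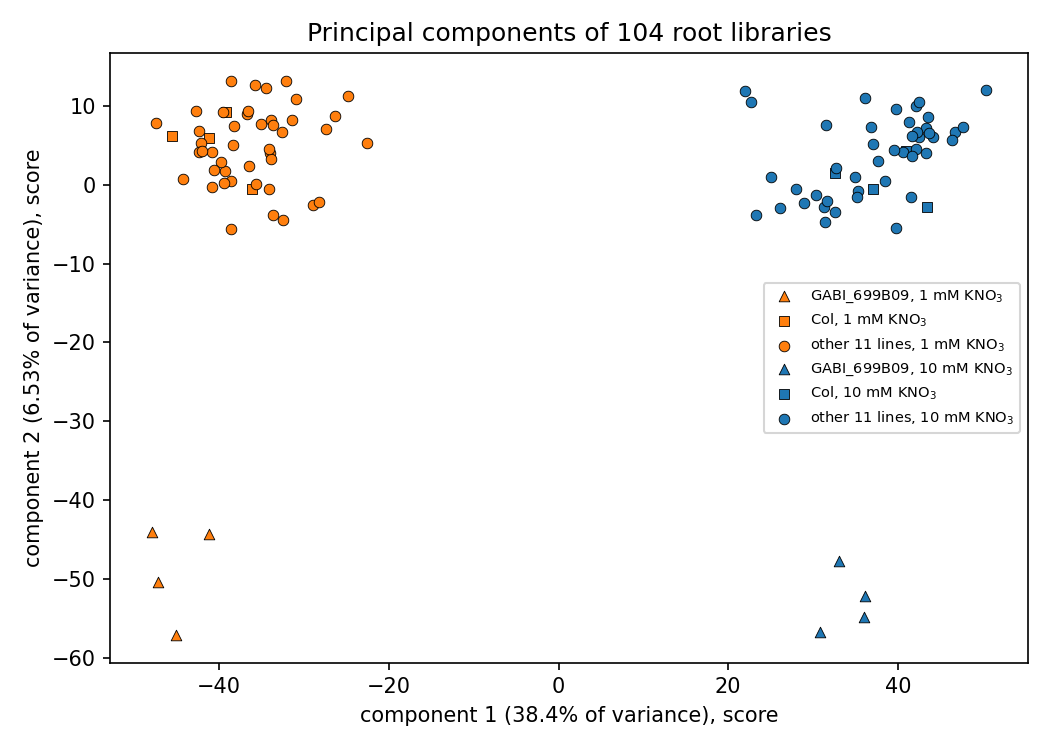
Scores of the libraries of all 13 lines on the first and second principal components of log2 CPM, with the percentage of variance on each axis. The concentrations separate along the first component (38.4% of the variance) and the GABI_699B09 libraries lie apart along the second (6.53%).

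The labels name the insertion lines and not the genes that carry the insertions. For a pair of lines a disrupted gene was set down before the data were examined, from general knowledge of the stocks. MYB29 (AT5G07690) was low everywhere: its 90 counts in the 8 GABI_868_E02 libraries gave 1.3 ± 0.436 CPM (SD, n = 8), while the other 96 libraries held 4 counts together, in 4 libraries. RAV2 (AT1G68840) was at 9.48 ± 2.07 CPM (n = 8) in SALK_070847C and at 33.2 ± 6.72 CPM in the other 96 libraries. A tag near the 3′ end says nothing about the parts of a transcript upstream of it, so neither value shows whether a working transcript was made. In 6 lines the gene lowest against the other 12 lines was lower in all 8 libraries than in each of the other 96, as set out with the line comparisons.

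The response shared by all 13 lines was measured between 52 libraries at 1 mM and 52 at 10 mM, and each value is the mean ± SD of those libraries. BT2 rose from 9.26 ± 3.34 to 185 ± 49.5 CPM (log2 change 4.33 ± 0.07 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 2.94e-70). The uncharacterised gene AT4G39675 rose from 3.11 ± 0.881 to 156 ± 55.2 CPM (log2 change 5.64), NRT2.6 from 0.806 ± 0.578 to 21.6 ± 9.77 CPM (4.76) and the nitrate transporter gene NRT1.8 from 11 ± 4.95 to 87.0 ± 31.0 CPM (3.01). In the other direction, NRT2.4 went from 12.4 ± 4.13 to 0.408 ± 0.301 CPM (log2 change -4.98 ± 0.12 SE), AT5G38910 from 25.4 ± 11.6 to 0.607 ± 0.553 CPM (-5.50), UMAMIT36 from 47.5 ± 8.42 to 1.76 ± 0.911 CPM (-4.78) and SAG13 from 30.4 ± 8.91 to 1.90 ± 1.42 CPM (-4.09). The other genes with the largest rises were AT2G21210 (3.6), AT5G56100 (3.57), MYBL2 (3.45), AT4G29905 (3.27), SNG1 (3.19), AT2G22122 (3.19), AT5G33355 (3.17) and AT1G49500 (3.02). The other large falls were those of NRT2.2 (-4.80), CYP71B22 (-4.46), AT4G01380 (-4.40), AOX1D (-4.33), AT4G37290 (-4.27), AT3G55677 (-4.20), AT4G01390 (-4.18) and UMAMIT19 (-4.17). Each of these 24 genes changed in the same direction in all 13 lines, which the rule for naming them required. Of the 19664 genes tested, 12675 were called, 6700 higher and 5975 lower at 10 mM, and 1252 of them changed at least 2-fold.

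Because most strips held a single concentration, the response was measured again among the 24 libraries, 12 at each concentration, of the 3 strips that held both. There 6955 genes were called by edgeR. Of the 12675 genes called over all lines, 12259 (96.7%) had the same sign within these strips, and so had all 1252 genes that changed at least 2-fold, of which 1203 were called again. The 24 libraries are among those that called the genes, so part of this agreement is built in. The median ratio of their log2 changes within the 3 strips to those over all libraries was 0.978. With strip as a covariate in the model of all libraries 7563 genes were called, so the number of genes with small changes is tied to how the strips are handled. Of the genes named for this comparison, BRN2, CYCB1;4, F3PH, LAC17, LBD18, MYB12, MYB28, RAB18, SMB and SUC2 were called neither with strip as a covariate nor within the 3 strips. CHI was not called with the covariate, nor APL, CYCA1;1, IAA29, LHCB1.2, PLT2, SULTR1;1 and VND7 within the 3 strips.

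All 11 genes of the high-affinity nitrogen uptake list were lower at 10 mM. NRT2.6, which the list does not hold, rose by 4.76 on the log2 scale. NRT2.5 went from 2.91 ± 1.65 to 0.0520 ± 0.0807 CPM (log2 change -5.70), NRT2.4 by -4.98 on the same scale, NRT2.2 from 18.7 ± 4.66 to 0.681 ± 0.428 CPM (-4.80) and AMT1;5 from 0.674 ± 0.370 to 0.0200 ± 0.0536 CPM (-4.60), while the abundant NRT2.1, chosen after its values were seen, fell from 776 ± 111 to 341 ± 61.1 CPM (-1.19). The list stood apart from the other genes in the camera test (adjusted p of 3.37e-13), and with the correlation between its genes estimated from the data the adjusted p was 4.52e-06. NRT2.1 and NRT2.2 are near-identical copies whose counts the deposited counting could have split, so the value of each is uncertain. Adjusted over the list alone, the same number, 11, fell.

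**Figure D2:**
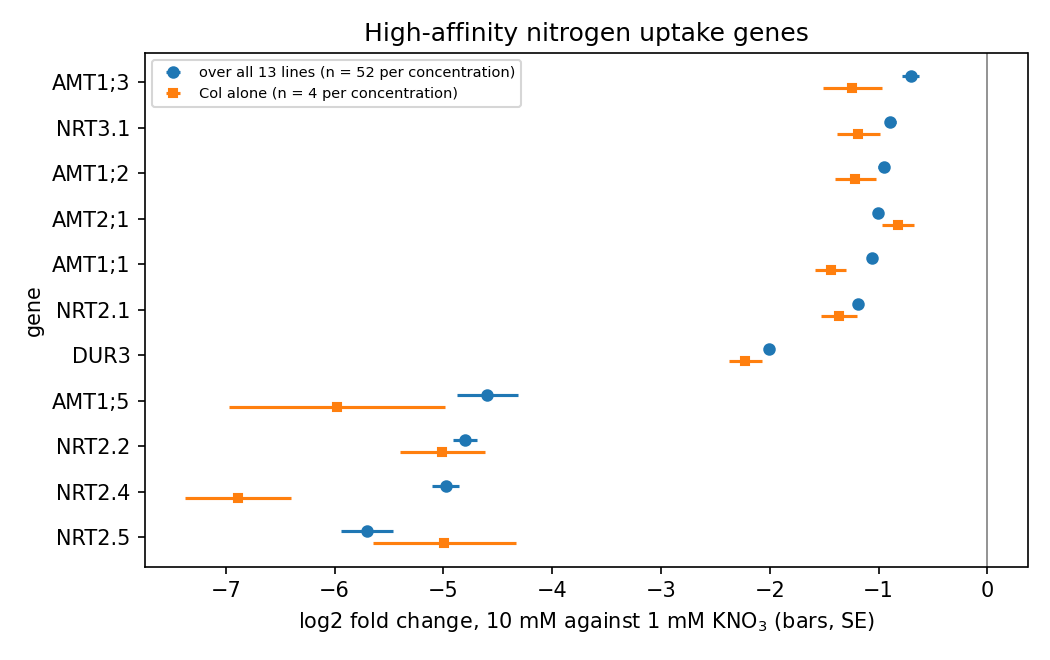
Log2 changes of high-affinity nitrogen uptake genes at 10 mM against 1 mM KNO3, over all lines and in Col alone, with bars for the standard errors. Over all lines NRT2.1 changed by -1.19 and NRT2.4 by -4.98.

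Genes of nitrogen metabolism and its regulators moved in both directions. In nitrate reduction and reductant supply 3 genes rose and 10 fell: NIA2 went from 352 ± 54.2 to 86.3 ± 14.4 CPM (log2 change -2.03) while NIA1 rose from 209 ± 29.8 to 487 ± 91.6 CPM (1.22). RFNR2 (-0.89) and PGD3 (-0.74) fell. In ammonium assimilation and amide synthesis 4 rose, 12 fell and 4 were not called, and adjusted over the list alone 5 rose and 13 fell. GDH3 fell from 15.7 ± 3.55 to 1.70 ± 0.498 CPM (-3.20), GLN1;4 from 123 ± 25.7 to 44.7 ± 7.72 CPM (-1.45) and GLN1;2 from 1434 ± 256 to 812 ± 126 CPM (-0.82), and ASN1 rose from 9.55 ± 5.24 to 18.4 ± 16.4 CPM (0.91), a call that was lost when replicate 1 of every group was left out. Of the nitrate-responsive regulators 13 rose, 4 fell and 3 were not called, led by BT2, BT1 (18.8 ± 5.87 to 146 ± 37.2 CPM, 2.98), LBD39 (15.8 ± 4.32 to 73.5 ± 13 CPM, 2.23) and NAC4 (1.6). Among cytokinin response genes 9 rose, 2 fell and 2 were not called: IPT5 (1.26), IPT3 (0.75) and CYP735A2 (0.72) rose and ARR16 (-0.98) fell. Camera adjusted p was 0.00113 for nitrate reduction, 0.00179 for ammonium assimilation, 1.15e-04 for the regulators and 0.00179 for cytokinin response. With the correlation estimated from the data the adjusted p was 0.0565 for each of these 4 lists, above 0.05, and none was called. Adjusted over the list alone, 3 rose and 10 fell in nitrate reduction, 13 rose and 4 fell among the regulators, and 9 rose and 2 fell in cytokinin response.

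Indole glucosinolate synthesis was lower at 10 mM: 1 gene rose, 10 fell and 2 were not called, with the same counts adjusted over the list alone. CYP81F2 fell from 87.9 ± 29.0 to 9.61 ± 7.02 CPM (log2 change -3.32), IGMT2 from 170.4 ± 51.6 to 32.6 ± 20.3 CPM (-2.41), MYB122 from 30.4 ± 6.89 to 6.14 ± 1.80 CPM (-2.30) and MYB51 from 25.0 ± 6.43 to 5.25 ± 2.11 CPM (-2.25). Its camera adjusted p was 7.03e-08, and 0.0345 with an estimated correlation. All 18 markers of photosynthetic tissue in the test, of 22 listed, rose, also adjusted over the list alone: LHCB1.3 from 1.27 ± 1.07 to 3.77 ± 2.67 CPM (1.64), LHCB1.2 by 1.54, RBCS1A from 8.69 ± 3.32 to 23.8 ± 8.21 CPM (1.47) and LHCA3 from 4.19 ± 1.64 to 11.7 ± 4.33 CPM (1.47). Counts of the LHCB1 and RBCS genes are uncertain because near-identical copies share tags. Of the root hair markers 1 rose and 7 fell, among them RHS19 (59.8 ± 12.2 to 27.7 ± 5.80 CPM, -1.11), LRX1 (-0.73), PRP3 (-0.69) and EXPA18 (-0.64). All 8 markers of xylem and secondary wall rose, by small amounts: VND7 by 0.57, XCP1 by 0.39, LAC17 by 0.34 and LAC4 by 0.33. The camera adjusted p of these 3 marker lists was 1.78e-08 for photosynthetic tissue, 0.00459 for root hair and 0.00725 for xylem. With an estimated correlation it was 0.0687, 0.162 and 0.162 in that order, and none of the 3 was called. Adjusted over the list alone, 1 root hair marker rose and 7 fell, and 8 xylem markers rose.

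Camera did not call the other lists over all lines, although in some of them most genes moved the same way. For sulfate starvation (adjusted p of 0.226) 3 genes rose and 8 fell: SULTR1;2 rose from 17.6 ± 4.01 to 53.7 ± 7.42 CPM (1.62), while SULTR2;1 (90.7 ± 21.8 to 28.9 ± 11.8 CPM, -1.66), LSU1 (-1.0) and SULTR1;1 (-0.99) fell. In iron deficiency (0.156) 8 rose and 3 fell: BHLH100 (2.45), IRT1 (2.18 ± 1.13 to 10.9 ± 4.30 CPM, 2.32) and FRO2 (1.75) rose and F6H1 (347 ± 78.8 to 68.6 ± 19.8 CPM, -2.34) fell. For phosphate starvation (0.782) 7 rose and 6 fell: PHO1;H1 (2.66) and PHT1;2 (1.63, a near-identical copy of PHT1;1 and so uncertain) rose, and SPX3 (-2.91) and RNS1 (-1.46) fell, with a median log2 change of -0.02 although the test's direction was up. Of the aliphatic glucosinolate genes (0.0970) 1 rose and 10 fell: SOT17 (-1.09), GSTU20 (-0.85) and FMOGSOX1 (-0.63) fell and MYB28 (0.37) rose. Among the genes of low oxygen response (0.335) 2 rose and 6 fell: PDC1 (-1.80), ADH1 (-1.47) and HB1 (-0.78) fell and HRE1 (0.95) rose. For jasmonate response (0.253) 2 rose and 4 fell: VSP1 (1.2) and VSP2 (0.94) rose and JAZ5 (-0.99) and JAZ1 (-0.82) fell. In abscisic acid and dehydration response (0.260) 5 rose and 1 fell, the largest changes being those of RAB18 (1.52, but 1.11 at an adjusted p of 0.101 with strip as a covariate), KIN1 (0.98, uncertain beside its copy KIN2), HAI1 (0.55, but 0.0481 and not called without replicate 1 of every group) and COR47 (0.37). Of the auxin response genes (0.0757) 6 rose and 0 fell by edgeR, with GH3.3 (1.58), IAA29 (0.93), IAA2 (0.85) and LBD18 (0.20) the largest.

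Tissue and pigment lists likewise gave no call over all lines. Of the flavonoid and anthocyanin genes (adjusted p of 0.464) 1 rose and 3 fell: CHI (-0.48), FLS1 (-0.45) and F3PH (-0.40, which changed sign when replicate 1 of every group was left out) fell and MYB12 (0.18, not called without replicate 2 or replicate 4) rose. For endodermis and suberin (0.975) 8 rose and 5 fell: CASP5 rose from 13.7 ± 5.47 to 54.2 ± 13.7 CPM (2.01), and FAR4 (-1.02), FAR5 (-1.0) and FAR1 (-0.46) fell, with a median log2 change of 0.13 and a mean of 0.02 although the test's direction was down. Among markers of dividing cells and meristem (0.708) 3 rose and 3 fell: PLT1 (0.38) and PLT2 (0.24) rose and CYCB1;4 (-0.27) and CYCA1;1 (-0.27) fell. The phloem markers (0.316) PP2-A1 (0.43), SEOR1 (0.40) and APL (0.19) rose and SUC2 (-0.24) fell. Of the 3 root cap markers (0.559) SMB (0.23) and BRN2 (0.19) rose. The seed list had 1 gene in the test, OLEO1, and was not tested. For each of the 14 lists without a call the counts adjusted over the list alone were the same as those over all genes.

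In Col alone, 4 libraries at each concentration were compared and values are mean ± SD (n = 4). NRT2.6 rose from 0.317 ± 0.163 to 25.8 ± 11.9 CPM (log2 change 6.22 ± 0.69 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 4.12e-12). BT2 rose from 7.57 ± 3.05 to 209.7 ± 53.4 CPM (4.83 ± 0.26 SE) and AT4G39675 from 2.97 ± 0.909 to 165 ± 27.2 CPM (5.80). NRT2.4 fell from 17.7 ± 6.99 to 0.118 ± 0.159 CPM (-6.89 ± 0.48 SE), AT5G38910 from 30.0 ± 16 to 0.343 ± 0.248 CPM (-6.38) and NRT2.2 from 18.8 ± 2.87 to 0.603 ± 0.233 CPM (-5.01). Other large rises in Col were those of AT5G56100 (4.33), AT2G21210 (4.21), MYBL2 (3.57), AT4G29905 (3.5), AT2G22122 (3.46), SNG1 (3.42) and AT3G23880 (3.36). Other large falls in Col were those of AT5G19880 (-5.26), AT4G10150 (-5.02), UMAMIT36 (-4.71), AT4G37290 (-4.42), RK3 (-4.39), SCRL26 (-4.37) and AT3G55665 (-4.26). In all, 4771 of 19664 genes were called, 2303 higher and 2468 lower at 10 mM, 1459 of them by at least 2-fold. In simulated counts with the depth of these libraries, 36% of genes changed 1.5-fold and 86% of genes changed 2-fold were called in this comparison, so changes under 2-fold were called in part. The simulated changed genes had at least 5 CPM on average and no strip effect, so the shares may be lower for the genes tested. With strip as a covariate 5144 genes were called in Col.

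Camera called 8 lists in Col. All 11 uptake genes fell, also adjusted over the list alone, led by NRT2.4 (-6.89), AMT1;5 (0.950 CPM at 1 mM and listed at 0 at 10 mM), NRT2.2 (-5.01) and NRT2.5 (-4.99). Of the indole glucosinolate genes 0 rose and 10 fell by edgeR, and adjusted over the list alone 1 rose and 10 fell, with CYP81F2 (-3.57), IGMT2 (-2.94), MYB51 (-2.14) and MYB122 (-2.11) the largest. In ammonium assimilation 2 rose and 8 fell, the same adjusted over the list alone, with GDH3 (-3.47), GLN1;4 (-1.74), GLU1 (1.33) and ASN1 (1.19, not called). The call of GLU1 was lost with DESeq2 (adjusted p of 0.0671), with limma-voom (0.0801), without a low-count filter and without any 1 of the 4 replicate numbers. In nitrate reduction 1 rose and 8 fell, and 2 rose and 8 fell adjusted over the list alone, with NIA2 (-2.42), NIA1 (1.32), RFNR2 (-1.16) and PGD3 (-0.88). Of the regulators 11 rose and 1 fell, the same adjusted over the list alone, with BT2 (4.83), BT1 (3.3), LBD39 (2.35) and LBD38 (1.43). Camera adjusted p was 1.00e-17 for uptake, 6.74e-09 for indole glucosinolates, 1.83e-04 for ammonium assimilation, 1.79e-04 for nitrate reduction and 3.28e-06 for the regulators. These 5 lists were also called with an estimated correlation, at adjusted p of 8.80e-08 for uptake, 0.0165 for indole glucosinolates and 0.0213 for the other 3. Cytokinin response (7 rose, and 8 adjusted over the list alone), photosynthetic tissue (13 rose, and 16 adjusted over the list alone) and root hair (5 fell, and 7 adjusted over the list alone) were called at 0.0175, 1.34e-06 and 7.45e-04. Each of these 3 had an adjusted p of 0.128 with an estimated correlation and was then not called. The largest changes were IPT5 (1.58), IPT3 (1.29), CYP735A2 (0.78) and ARR5 (0.70) for cytokinin response, LHCB1.2 (0.0467 to 1.28 CPM), LHCB1.1 (2.89, not called), LHCB1.3 (2.65) and RBCS3B (1.90, not called) for photosynthetic tissue and RHS19 (-1.30), PRP3 (-1.02), LRX1 (-0.90) and EXPA18 (-0.72) for root hair. The calls of LHCB1.2 and LHCB1.3 were lost without replicate 2 of every group (adjusted p of 0.381 and 0.396 by edgeR).

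Camera called none of the other 14 lists in Col. In 3 of them the largest changes were those of BHLH100 (listed at 0 at 1 mM and at 0.542 CPM at 10 mM), IRT1 (2.59), BHLH38 (2.49) and F6H1 (-2.41) among iron deficiency genes, PHO1;H1 (3.27), SPX3 (-3.18), PHT1;2 (2.73) and MGD3 (-1.94) among phosphate starvation genes and CASP5 (1.74), FAR4 (-1.17), FAR5 (-1.16) and ASFT (-0.95) among endodermis markers. PDC1 (-2.18) and ADH1 (-1.97) of low oxygen response, GH3.3 (1.94) of auxin response, SULTR1;2 (1.64) of sulfate starvation and VSP1 (1.36) of jasmonate response were also called. By edgeR, 1 rose and 0 fell for abscisic acid response (adjusted p of 0.376), 0 rose and 2 fell for aliphatic glucosinolates (adjusted p of 0.376), 2 rose and 0 fell for auxin response (adjusted p of 0.197), 0 rose and 0 fell for flavonoids (adjusted p of 0.496) and 5 rose and 1 fell for iron deficiency (adjusted p of 0.135). Further, 1 rose and 4 fell for jasmonate response (adjusted p of 0.347), 1 rose and 3 fell for low oxygen response (adjusted p of 0.425), 1 rose and 1 fell for dividing cells (adjusted p of 0.563), 2 rose and 6 fell for endodermis (adjusted p of 0.114) and 2 rose and 1 fell for phloem (adjusted p of 0.376). Lastly, 1 rose and 0 fell for root cap (adjusted p of 0.376), 0 rose and 0 fell for xylem (adjusted p of 0.496), 5 rose and 5 fell for phosphate starvation (adjusted p of 0.852) and 2 rose and 3 fell for sulfate starvation (adjusted p of 0.376). Adjusted over the list alone, 2 jasmonate genes rose and 4 fell, 1 marker of dividing cells rose and 2 fell, and the other 12 lists had the same counts.

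Each insertion line was compared with Col, averaged over the concentrations, with 8 libraries per side, and values are mean ± SD (n = 8). The 8 libraries are of both concentrations. For a gene that changes with nitrate, the SD and any overlap of libraries therefore also hold that change. All 12 comparisons use the same 8 Col libraries, so a gene that stands out in Col appears in many of them. AT3G25150 was at 33.0 ± 11.2 CPM in Col and between 71.5 and 83.6 CPM in the means of the 12 lines, and ARP9 was at 12.8 ± 2.61 CPM in Col and between 4.18 and 8.16 CPM in the lines. One or both were among the 3 genes furthest up or down in most SALK lines, as were AT5G35935 (3.04 ± 0.474 CPM in Col) and AT5G46295 (2.24 ± 1.83 CPM), and in 4 of these lines AT5G08250 (13.8 ± 6.52 CPM), whose line values are given by line. AT5G35935 does not set Col apart from all lines, since it averaged 1.75 ± 1.71 CPM in the 32 GABI and SAIL libraries. Adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the 19664 genes. With strip as a covariate in the edgeR model more genes were called in each line than without it (in parentheses): 611 in GABI_513E07 (303), 3080 in GABI_699B09 (2285), 400 in GABI_868_E02 (35), 184 in SAIL_1207_H04 (26), 585 in SALK_012253 (125) and 252 in SALK_015182 (45). With it the number was 1040 in SALK_035980 (70), 755 in SALK_070847C (119), 1425 in SALK_085964C (53), 247 in SALK_094437C (24), 83 in SALK_100002 (10) and 77 in SALK_146141 (42).

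In GABI_513E07, AT5G27500 was at 12.2 ± 1.40 CPM, with 802 counts in the line and 2 in the 8 Col libraries. AT2G05995 was at 7.39 ± 4.73 CPM (476 counts against 3), and AT4G08593 at 15.4 ± 17.0 CPM (1041 counts against 3), the latter above every Col library in 4 of 8 libraries and not called by limma-voom (adjusted p of 0.0649). AT4G31310 was lower, at 22.0 ± 1.76 CPM against 61.2 ± 6.79 CPM in Col (log2 difference -1.48), as were AT1G55675 at 9.54 ± 3.13 CPM against 26.5 ± 9.25 CPM in Col (-1.46) and AT1G09910 at 4.88 ± 1.18 CPM against 12.4 ± 2.38 CPM in Col (-1.33). The 3 lower genes lay under every Col library in 8 of 8 libraries. In this line 303 genes were called, 133 higher and 170 lower.

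GABI_699B09 differed from Col in the most genes. AT3G28320 was at 53.8 ± 15 CPM against 0.107 ± 0.109 CPM in Col (log2 difference 8.76), AT1G12340 at 16.2 ± 2.2 CPM with 1269 counts against 3 in Col, and AT1G19550 at 12.3 ± 3.26 CPM against 0.107 ± 0.150 CPM in Col. AT5G51620 was nearly absent at 0.554 ± 0.136 CPM against 26.4 ± 3.46 CPM in Col (log2 difference -5.51), AT3G53650 was at 0.589 ± 0.405 CPM against 22.8 ± 5.78 CPM in Col (-5.43) and AT3G47675 at 0.167 ± 0.130 CPM against 7.84 ± 1.92 CPM in Col (-5.42). Each of the 6 genes lay beyond every Col library in 8 of 8 libraries (adjusted p of 1.77e-53 for AT5G51620, edgeR). In all, 2285 genes were called, 897 higher and 1388 lower, and 601 of them differed at least 2-fold. The called genes were grouped along the chromosomes: of 197 windows of 100 neighbouring genes, 47 held at least 20% called genes, and the highest window held 54%.

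**Figure D3:**
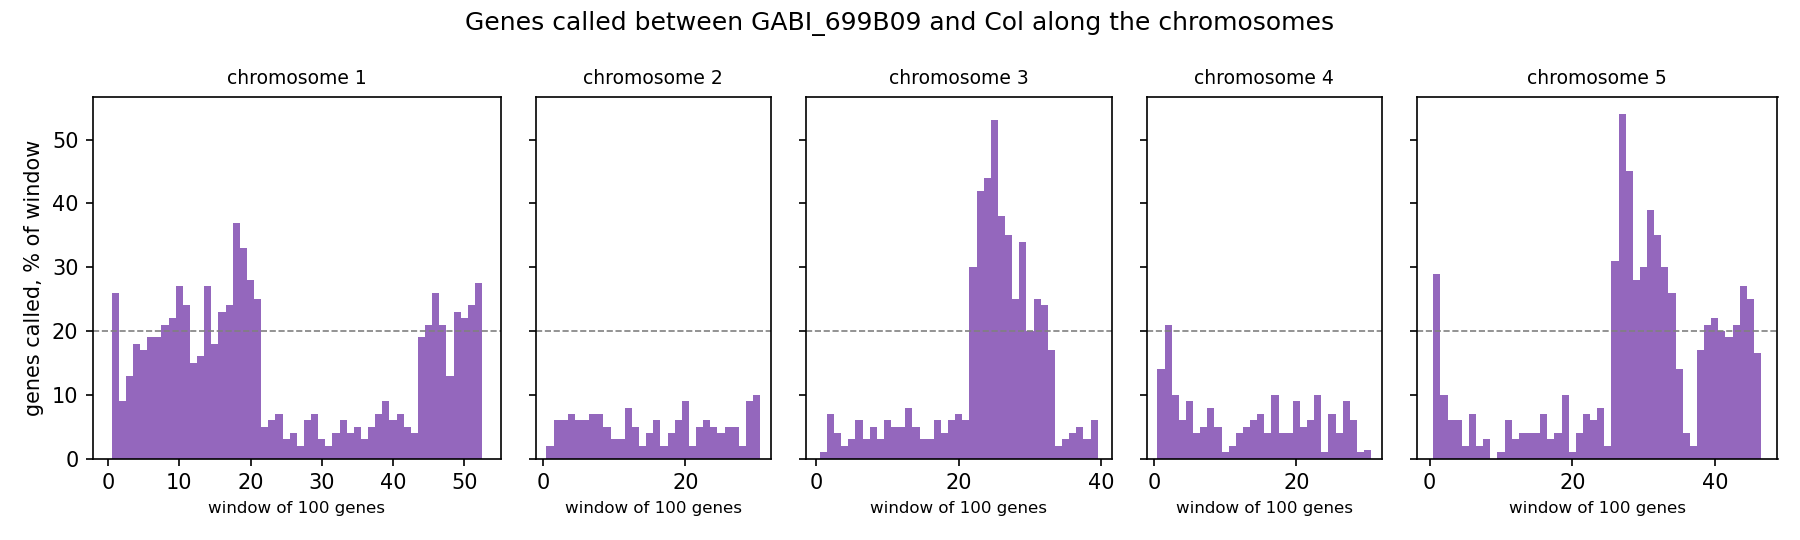
Percentage of genes called between GABI_699B09 and Col in each of 197 windows of 100 neighbouring genes, along the 5 chromosomes, with a dashed line at 20%. Runs of at least 3 windows at or above 20% form 6 blocks on 3 chromosomes, where a single lower window inside a run was allowed. Single windows outside the blocks also reach 20%, on chromosomes 1 (26%), 4 (21%) and 5 (29%). The highest window holds 54%.

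In GABI_868_E02, MRD1 was at 164 ± 20.9 CPM against 1.82 ± 0.439 CPM in Col (log2 difference 6.49), AT2G01422 at 5.57 ± 1.97 CPM against 1.34 ± 0.504 CPM in Col (2.0) and HEI10, the neighbour of MRD1, at 15.5 ± 3.49 CPM against 4.90 ± 1.11 CPM in Col (1.69). AT2G45030 was lower at 2.27 ± 0.536 CPM against 7.50 ± 2.4 CPM in Col (-1.72, adjusted p of 3.73e-10 by edgeR), and ARP9 was at 6.95 ± 1.48 CPM. AT3G55677 was lower on the fitted scale (-1.11 ± 0.26 SE), but at 11.7 ± 11.9 CPM against 17.2 ± 16 CPM in Col the libraries overlapped. With 35 genes called, 21 higher and 14 lower, the count rested on single Col libraries: it was 18 without Col 10 mM replicate 2, 17 without Col 10 mM replicate 3, 62 without Col 10 mM replicate 4, 89 without Col 1 mM replicate 1 and 18 without Col 1 mM replicate 2.

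In SAIL_1207_H04, MRD1 was at 166 ± 25.5 CPM against 1.82 ± 0.439 CPM in Col (log2 difference 6.50) and QQS, a gene known from Arabidopsis alone, at 47.4 ± 11.5 CPM against 1.74 ± 0.433 CPM in Col (4.74 ± 0.18 SE, adjusted p of 3.65e-40 by edgeR). CBP60G was at 12.3 ± 12.1 CPM against 5.29 ± 5.14 CPM in Col (1.85), above every Col library in 3 of 8 libraries. That call was lost without replicate 4 (0.40, adjusted p of 0.870 by edgeR) and with limma-voom (1.1, adjusted p of 0.296). AT5G05200 was lower at 14.6 ± 1.54 CPM against 29.0 ± 1.91 CPM in Col (-0.99), and so was the auxin response factor gene ARF9 at 48.1 ± 21.3 CPM against 91.3 ± 39.4 CPM in Col (-0.93), under every Col library in 4 of 8 libraries. ARP9 was at 7.55 ± 1.22 CPM. The line gave 26 called genes, 17 higher and 9 lower.

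In SALK_012253, AT5G08250 was at 4.77 ± 2.25 CPM (-1.54) and MYB9 at 4.02 ± 1.21 CPM against 6.63 ± 0.989 CPM in Col (-0.70 ± 0.15 SE), while AT5G35935 was higher at 9.21 ± 1.5 CPM (1.59), AT5G46295 at 5.45 ± 3.14 CPM and AT3G25150 at 83.0 ± 18.6 CPM (1.39). ARP9 was at 7.20 ± 0.838 CPM. There were 125 called genes, 47 higher and 78 lower. The count was 25 without Col 10 mM replicate 2, 29 without Col 10 mM replicate 3, 338 without Col 10 mM replicate 4, 305 without Col 1 mM replicate 1, 26 without Col 1 mM replicate 2 and 73 without Col 1 mM replicate 4.

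In SALK_015182, the ERF-family gene AT5G61590 was nearly absent at 2.46 ± 0.488 CPM against 126 ± 80.3 CPM in Col (log2 difference -5.39), under every Col library in 8 of 8 libraries (adjusted p of 1.49e-48 by edgeR). GLIP3 was lower at 7.64 ± 4.74 CPM against 13 ± 2.52 CPM in Col (-1.02) and AT5G35940 at 17.3 ± 7.30 CPM against 32.5 ± 4.46 CPM in Col (-0.90). AT3G29410 was higher at 15.4 ± 5.89 CPM against 6.43 ± 2.13 CPM in Col (1.31), AT5G35935 was at 13.3 ± 3.18 CPM and AT3G25150 at 75.6 ± 19.1 CPM. With 45 genes called, 16 higher and 29 lower, single Col libraries again mattered: the count was 24 without Col 10 mM replicate 2, 24 without Col 10 mM replicate 3, 76 without Col 10 mM replicate 4 and 23 without Col 1 mM replicate 2.

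In SALK_035980, AT1G76510 was at 0.872 ± 0.432 CPM against 13 ± 2.03 CPM in Col (log2 difference -3.97), under every Col library in 8 of 8 libraries (adjusted p of 2.38e-41 by edgeR). SADHU3-2 was higher at 12.1 ± 1.19 CPM against 5.25 ± 1.07 CPM in Col (1.19), AT5G35935 was at 9.08 ± 1.14 CPM, AT3G25150 at 83.6 ± 17.6 CPM, ARP9 at 8.07 ± 1.2 CPM and AT1G74300 at 3.53 ± 0.929 CPM against 5.69 ± 1.42 CPM in Col (-0.65). Of 70 called genes 27 were higher and 43 lower. Their number was 29 without Col 10 mM replicate 2, 29 without Col 10 mM replicate 3, 154 without Col 10 mM replicate 4, 28 without Col 1 mM replicate 2 and 42 without Col 1 mM replicate 4.

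In SALK_070847C, BGLU34 was at 4.50 ± 1.51 CPM against 40.5 ± 9.64 CPM in Col (log2 difference -3.19), RAV2 at 9.48 ± 2.07 CPM against 36.3 ± 2.66 CPM in Col (-1.96) and AT1G08040 at 11 ± 1.56 CPM against 23.4 ± 2.74 CPM in Col (-1.12), each under every Col library in 8 of 8 libraries. LHCB1.3 was higher at 5.07 ± 4.0 CPM against 1.58 ± 2.07 CPM in Col (2.04 ± 0.45 SE), PSAL at 12.5 ± 8.41 CPM against 4.52 ± 3.09 CPM in Col (1.52) and AT5G46295 at 5.28 ± 4.15 CPM, with 3, 2 and 3 of 8 libraries above every Col library. The line gave 119 called genes, 69 higher and 50 lower. Left-out libraries changed the count to 53 without Col 10 mM replicate 2, 77 without Col 10 mM replicate 3, 185 without Col 10 mM replicate 4 and 75 without Col 1 mM replicate 2.

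In SALK_085964C, AT5G27550 was at 2.37 ± 0.886 CPM against 7.58 ± 1.2 CPM in Col (log2 difference -1.68), under every Col library in 8 of 8 libraries (adjusted p of 9.47e-14 by edgeR). AT5G35935 was at 12.6 ± 2.30 CPM (2.03), AT5G46295 at 5.89 ± 3.59 CPM and AT3G25150 at 83.2 ± 14.5 CPM. AT5G08250 was at 6.43 ± 2.49 CPM and ARP9 at 7.26 ± 1.2 CPM. There were 53 called genes, 24 higher and 29 lower. These became 15 without Col 10 mM replicate 2, 21 without Col 10 mM replicate 3, 225 without Col 10 mM replicate 4, 179 without Col 1 mM replicate 1, 16 without Col 1 mM replicate 2, 27 without Col 1 mM replicate 3 and 22 without Col 1 mM replicate 4.

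In SALK_094437C, AT5G35935 was at 12.6 ± 2.19 CPM (2.04), AT5G46295 at 5.70 ± 5.15 CPM and AT3G25150 at 77.6 ± 18.2 CPM. ARP9 was at 6.75 ± 1.51 CPM (-0.90), AT5G08250 at 7.05 ± 2.28 CPM and AT3G32040 at 30.9 ± 12.6 CPM against 42.9 ± 19.3 CPM in Col (-0.44 ± 0.10 SE). It had 24 called genes, 17 higher and 7 lower. That number became 12 without Col 10 mM replicate 2, 39 without Col 1 mM replicate 1 and 10 without Col 1 mM replicate 3.

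In the comparison as first fitted SALK_100002 gave the fewest called genes, though SALK_146141 gave fewer with strip as a covariate. AT5G35935 was at 13.2 ± 3.34 CPM (2.1), AT5G46295 at 6.43 ± 3.25 CPM and AT3G25150 at 83.0 ± 17.2 CPM. AT5G08250 was at 7.94 ± 4.44 CPM and ARP9 at 7.96 ± 0.777 CPM. Of 10 called genes 7 were higher and 3 lower, and without 1 library the count moved past 1.5 times in a single case, to 16 without Col 1 mM replicate 1.

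In SALK_146141, LBD4 was nearly absent at 0.523 ± 0.179 CPM against 19.2 ± 6.10 CPM in Col (log2 difference -5.20), under every Col library in 8 of 8 libraries (adjusted p of 1.69e-21 by edgeR). TBL36 was lower at 8.54 ± 1.49 CPM against 25.5 ± 8.44 CPM in Col (-1.53) and AT1G03820 at 7.46 ± 2.4 CPM against 20.9 ± 3.98 CPM in Col (-1.49). AT5G35935 was at 12.6 ± 2.04 CPM, AT5G46295 at 5.85 ± 3.15 CPM and AT3G25150 at 78.9 ± 18.9 CPM. Of 42 called genes 15 were higher and 27 lower.

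The gene lowest in each line against the other 12 lines together, with 8 against 96 libraries, was clear-cut in 6 lines, where all 8 libraries lay under each of the other 96: AT1G55675 in GABI_513E07 (9.54 ± 3.13 CPM against 27.4 ± 7.97 CPM), AT5G51620 in GABI_699B09 (0.554 ± 0.136 CPM against 26 ± 3.35 CPM), AT5G61590 in SALK_015182 (2.46 ± 0.488 CPM against 98.4 ± 55.5 CPM), AT1G76510 in SALK_035980 (0.872 ± 0.432 CPM against 11.9 ± 1.63 CPM), BGLU34 in SALK_070847C (4.50 ± 1.51 CPM against 37.4 ± 8.89 CPM) and LBD4 in SALK_146141 (0.523 ± 0.179 CPM against 23.0 ± 8.36 CPM). In GABI_868_E02 it was AT2G45030 (2.27 ± 0.536 CPM against 6.47 ± 1.68 CPM), with 6 of 8 libraries under the other 96. In SAIL_1207_H04 it was AT5G35935 (0.374 ± 0.168 CPM against 8.37 ± 5.02 CPM), which some other libraries also lacked. In Col, SALK_012253, SALK_085964C, SALK_094437C and SALK_100002 it was MRD1, which is low in every Col and SALK library. AT5G27550 in SALK_085964C, chosen after its values were seen, was at 2.37 ± 0.886 CPM against 8.02 ± 1.49 CPM in the other 96 libraries.

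**Figure D4:**
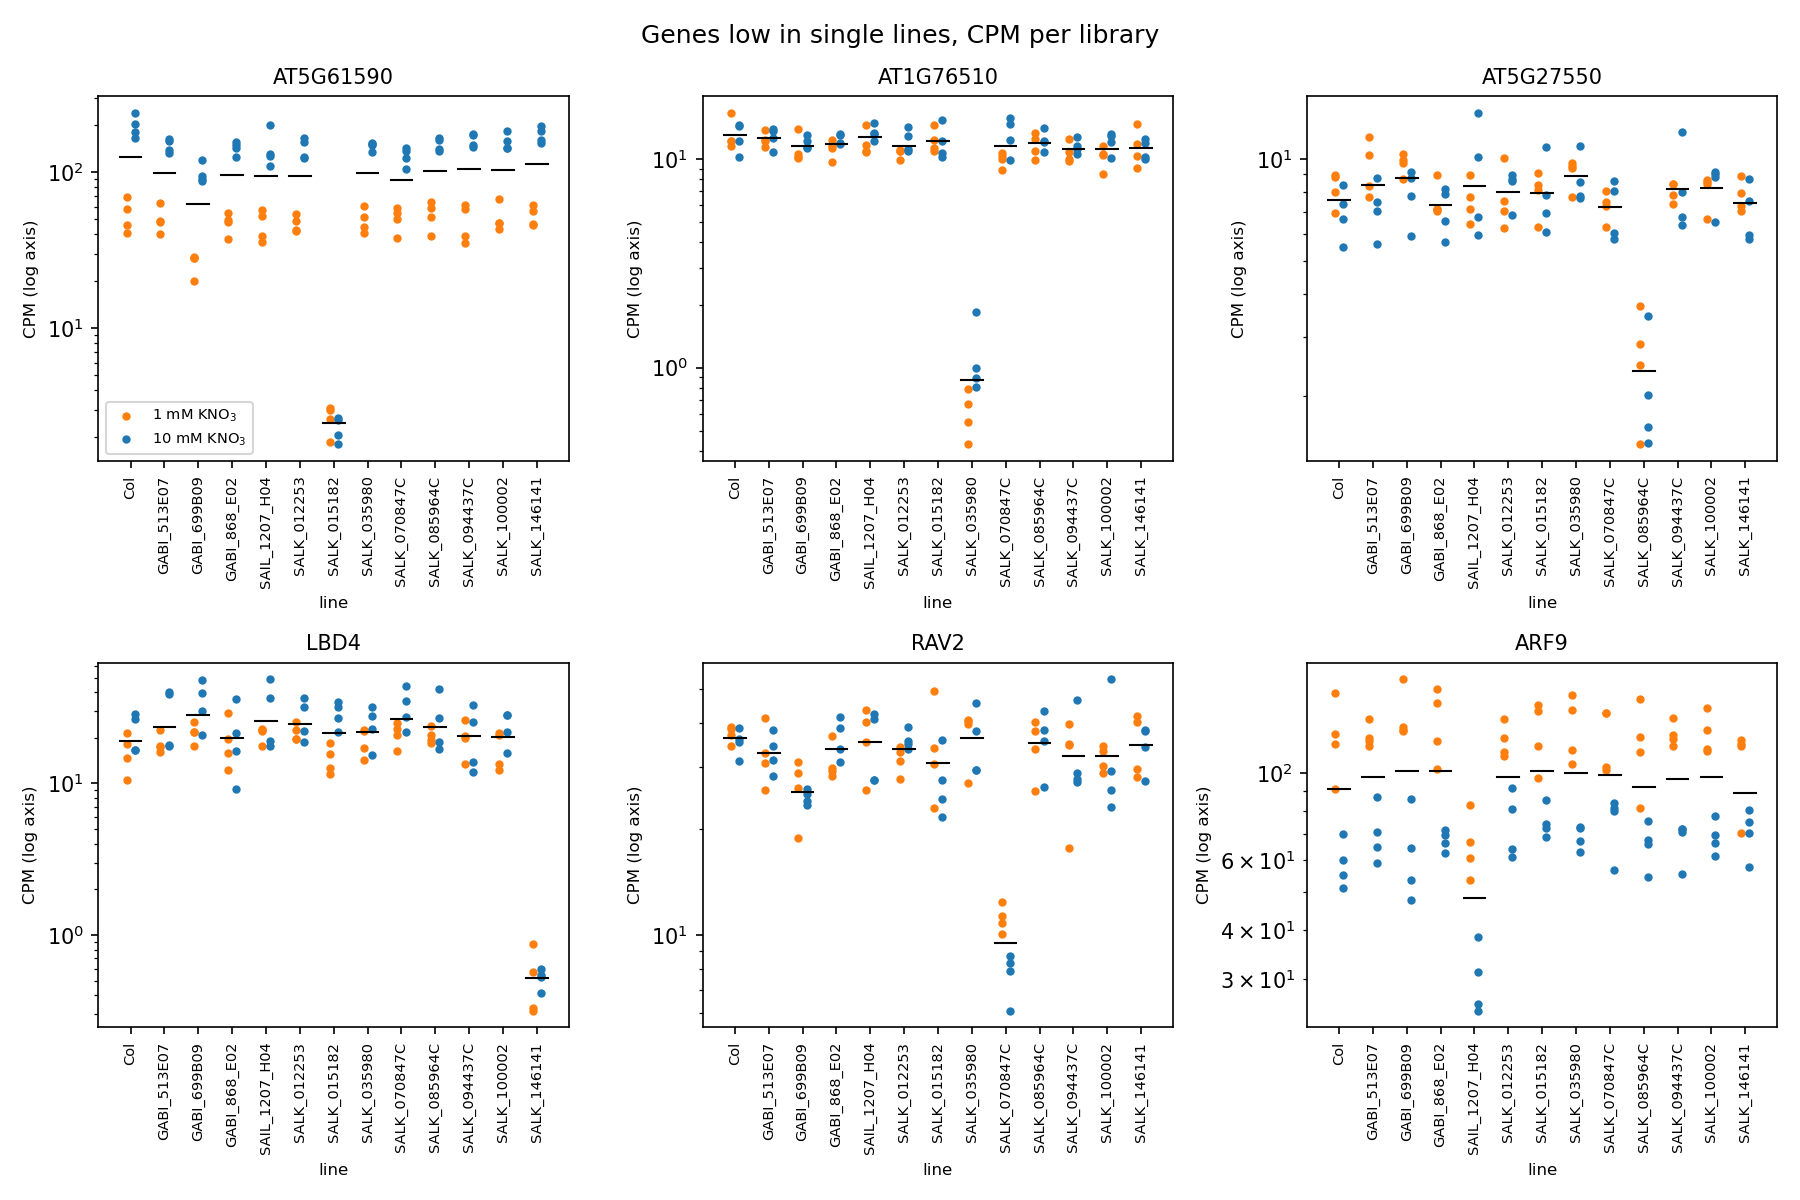
CPM per library, on a log axis, of AT5G61590, AT1G76510, AT5G27550, LBD4, RAV2 and ARF9 in the 13 lines, with bars at line means. AT5G61590 stands at 2.46 CPM in SALK_015182, AT1G76510 at 0.872 CPM in SALK_035980 and LBD4 at 0.523 CPM in SALK_146141.

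MRD1 (AT1G53480) separated the lines by the collection they come from, a pattern looked into after its values were seen. It was at 159 ± 20.1 CPM in the 32 GABI and SAIL libraries, with a range of 124 to 193 CPM, and at 2.23 ± 0.940 CPM in the 72 Col and SALK libraries, with a range of 0.978 to 5.50 CPM, a 71.2-fold difference in means. HEI10, the next gene along the chromosome, was at 15.6 ± 3.29 CPM against 5.61 ± 1.38 CPM, while the genes on either side of this pair hardly differed: MSL4 was at 7.91 ± 1.63 CPM against 8.92 ± 1.96 CPM and MUM4 at 19.4 ± 3.63 CPM against 19.7 ± 4.07 CPM. Of the 1198 genes called between the kinds of line by edgeR, MRD1 was the 1 gene whose libraries did not overlap. The GABI lines include GABI_699B09, which by itself differed from Col in 2285 genes. How many of the 1198 rest on that line was not tested, so their number does not measure a difference between collections.

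**Figure D5:**
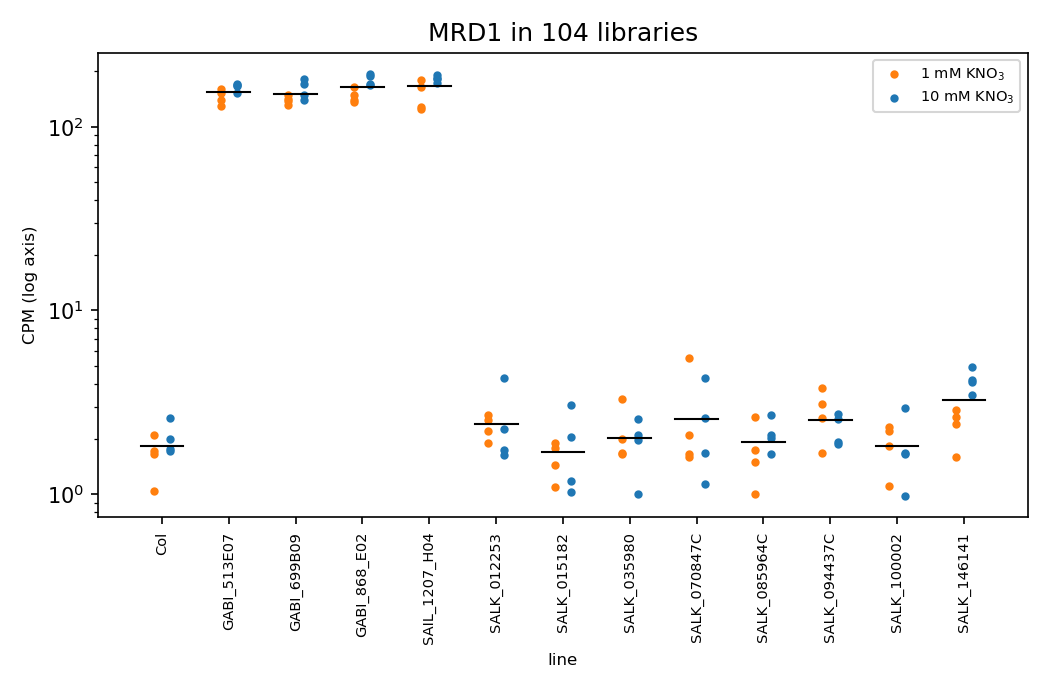
CPM of MRD1 per library, on a log axis, in the 13 lines. The 32 GABI and SAIL libraries lie between 124 and 193 CPM and the 72 Col and SALK libraries between 0.978 and 5.50 CPM.

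Across the 12 line comparisons camera called a list in 15 cases, and the members of these lists named as examples were chosen after their values were seen. Photosynthetic tissue markers were higher than in Col in SALK_070847C, where 7 of 18 rose (9 adjusted over the list alone), among them RBCS1A at 25.7 ± 14.3 CPM against 13.3 ± 8.31 CPM in Col and PSAD1 at 15.3 ± 8.06 CPM against 6.82 ± 2.68 CPM (n = 8). They were lower in GABI_699B09, where 7 fell (9 adjusted over the list alone), among them LHCA4 at 44.7 ± 20.1 CPM against 90.4 ± 41.5 CPM and PSBO1 at 21.2 ± 8.52 CPM against 39.8 ± 16.9 CPM. LHCA4 and PSBO1 lie in the line's blocks of called genes. There a lower transcript level could not be told from tags that no longer match the reference. In GABI_513E07 GAPA and GAPB rose (6 genes adjusted over the list alone), and in SALK_015182 and SALK_085964C no single marker was called, over all genes or adjusted over the list alone. In GABI_513E07 the call of GAPB was lost with strip as a covariate and without any 1 of the 4 replicate numbers. That of GAPA was lost without replicate 2, 3 or 4. The camera adjusted p for this list was 1.24e-12 in SALK_070847C, 0.00529 in GABI_699B09, 1.49e-05 in GABI_513E07, 0.0108 in SALK_015182 and 0.0161 in SALK_085964C. With the correlation estimated from the data it was 0.853 in SALK_070847C and 0.976 in the other 4, and none was called. Single libraries varied widely: in Col the mean log2 CPM of these markers was 1.63 ± 0.16 at 1 mM and 2.70 ± 0.53 at 10 mM (n = 4), and in SALK_070847C it was 2.37 ± 0.55 and 3.29 ± 0.65.

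Aliphatic glucosinolate genes were called as a list, with medians above Col, in SAIL_1207_H04 (median log2 difference 0.23, camera adjusted p of 9.18e-05), SALK_012253 (0.26, 0.00256), SALK_015182 (0.16, 0.00744), SALK_085964C (0.26, 0.00182) and SALK_146141 (0.31, 2.24e-08). With an estimated correlation the adjusted p was 0.976 in all 5 lines, and none was called. Single genes seldom passed: GSTU20 rose in SALK_012253, at 72.2 ± 23.6 CPM against 47.8 ± 15.4 CPM (n = 8), and adjusted over the list alone 6 genes rose in SALK_085964C, 3 in SALK_146141, 1 in SALK_012253 and none in SAIL_1207_H04 and SALK_015182. Endodermis and suberin markers were called as lower in SAIL_1207_H04 (median -0.13, 0.00499), SALK_100002 (-0.10, 0.0119) and SALK_146141 (-0.10, 0.0188), where 5, 3 and 2 genes fell adjusted over the list alone and none over all genes. The remaining calls were flavonoid and anthocyanin synthesis in SALK_035980 (median -0.31, 0.0466) and root hair markers in SALK_146141 (median -0.20, 0.0217), in both of which no single gene was called, over all genes or adjusted over the list alone. For these 5 calls too the adjusted p with an estimated correlation was 0.976. The other lists, those of nitrogen uptake, reduction and assimilation included, gave no call in any line, with a lowest camera adjusted p of 0.0806 for low oxygen response.

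Whether a line responds to nitrate as Col does was tested as the difference between the responses, with 4 libraries in each of 4 groups (mean ± SD, n = 4). In Col AT5G61590 rose from 53.3 ± 12.6 CPM at 1 mM to 198 ± 31.8 CPM at 10 mM, and in SALK_015182 it stayed at 2.64 ± 0.544 and 2.28 ± 0.416 CPM (log2 difference of responses -2.06 ± 0.32 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p of 1.81e-04). In the same line AT5G49840 went from 18.1 ± 1.31 to 16.9 ± 3.72 CPM, and in Col from 12.1 ± 1.21 to 22.1 ± 1.82 CPM (-0.97 ± 0.19 SE, adjusted p of 0.0207 by edgeR). NAC003 fell from 14.9 ± 1.94 to 2.84 ± 0.235 CPM in GABI_699B09 and from 22.1 ± 7.69 to 13.7 ± 1.61 CPM in Col (-1.68 ± 0.32 SE, adjusted p of 0.010 by edgeR). PHYA went from 47.4 ± 4.77 to 78.9 ± 7.92 CPM in GABI_868_E02 and from 82.3 ± 20.3 to 73.2 ± 6.45 CPM in Col (0.90 ± 0.18 SE, adjusted p of 0.0365 by edgeR). PHYA was not called with strip as a covariate (0.69, adjusted p of 0.138), with limma-voom (adjusted p of 0.0590) or without any 1 of the 4 replicate numbers (0.76 to 0.99, adjusted p of 0.0931 to 0.354). The fifth called gene, AT3G48840 in GABI_699B09, was named after its values were seen because no group reached 5 CPM: its highest group mean was 1.87 CPM (5.25 ± 0.95 SE, adjusted p of 0.00638 by edgeR), and a fitted value at so few counts depends on the prior count. The other 4 calls were each lost without some replicate number: AT5G61590 without replicate 4 (adjusted p of 0.0722), AT5G49840 without replicate 2, 3 or 4 (0.401, 0.870 and 0.0831), NAC003 without replicate 1, 3 or 4 (0.319, 0.288 and 0.249) and AT3G48840 without replicate 1, 2 or 4 (0.0822, 0.372 and 0.249). In the same order the log2 differences were -1.96 for AT5G61590 and -0.99, -0.69 and -1.05 for AT5G49840. They were -1.50, -1.67 and -1.67 for NAC003 and 6.46, 4.52 and 4.99 for AT3G48840. These fits have fewer libraries, so a lost call does not by itself show that a difference rests on 1 replicate.

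In the other 9 lines 0 genes differed from Col in their nitrate response by edgeR, and 0 by DESeq2 and by limma-voom, while edgeR with strip as a covariate called 2 in SALK_070847C, 1 in SALK_100002 and 3 in SALK_146141. At an unadjusted p under 0.05 edgeR gave 1137 in GABI_513E07, 1367 in SAIL_1207_H04, 885 in SALK_012253 and 787 in SALK_035980. It gave 863 in SALK_070847C, 1181 in SALK_085964C, 1056 in SALK_094437C, 558 in SALK_100002 and 1414 in SALK_146141. These are between 2.84% (SALK_100002) and 7.19% (SALK_146141) of the genes tested. With no true difference a share of about 0.05 would pass. The share was above that in GABI_513E07 (5.78%), SAIL_1207_H04 (6.95%), SALK_085964C (6.01%), SALK_094437C (5.37%) and SALK_146141 (7.19%). It was below that in the rest of these lines. Whether the higher shares reflect true differences was not tested. In simulated counts for SALK_012253, 8% of genes whose response differed 1.5-fold, 62% of those that differed 2-fold and 100% of those that differed 4-fold were called, so a shared response cannot be read from the absence of calls. With strip as a covariate the counts of called genes were higher in GABI_699B09 and SALK_015182 and 0 in GABI_868_E02, as given with the alternatives. The counts also moved with single libraries. For GABI_699B09, with 2 called genes, the count was 0 without Col 10 mM replicate 2 and 1 without Col 1 mM replicate 4. For GABI_868_E02, with 1, it was 0 without Col 10 mM replicate 1, 2 without Col 10 mM replicate 2, 0 without Col 10 mM replicate 4, 2 without Col 1 mM replicate 2, 0 without Col 1 mM replicate 3 and 0 without Col 1 mM replicate 4. For SALK_015182, with 2, it was 1 without Col 10 mM replicate 1, 1 without Col 10 mM replicate 2, 1 without Col 10 mM replicate 3, 1 without Col 1 mM replicate 3 and 1 without Col 1 mM replicate 4. Of the lines with 0 by edgeR, SALK_070847C gave 1 without Col 10 mM replicate 2 and 1 without Col 1 mM replicate 2, SALK_085964C gave 1 without Col 1 mM replicate 2 and SALK_146141 gave 1 without Col 1 mM replicate 2.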

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

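The counts of other splits and the tests of chromosome blocks, thinned depth, single libraries, collections and Col against 11 of the 12 lines were chosen after the results were seen, and the strip test of Col against the 12 insertion lines was set down before its result. In 78 tests of 26 groups of 4 libraries on 3 quantities, 3 libraries stood far from the rest of their group, where chance gives about 1 in 20. The total of SALK_146141 1 mM replicate 3 was 5.01e+06 counts and the nearest in its group 8.67e+06. The total of SALK_094437C 1 mM replicate 1 was 8.49e+06 and the nearest 6.08e+06. The mean log2 CPM of the high-affinity nitrogen uptake genes in SALK_015182 10 mM replicate 4 was 3.42 and the nearest 3.66, so uptake genes were a little lower in that library.

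For 5 genes the nitrate response of a line differed from that of Col by the test of the difference itself, and each of these calls was lost without some replicate number. AT5G61590 (log2 difference of responses -2.06) and AT5G49840 (-0.97) differed in SALK_015182, NAC003 (-1.68) and AT3G48840 (5.25) in GABI_699B09, and PHYA (0.90) in GABI_868_E02. When the libraries of each comparison were split in 100 other ways, the real one included, chance could not be excluded for the number of such genes in SALK_015182 (2 by limma-trend, highest other 35) or in GABI_868_E02 (1, highest other 19). For GABI_699B09 chance can be excluded only weakly (5, highest other 1544), since 12 lines were tested and the splits were drawn without regard to strip. What the split with 1544 genes reflects was not tested, since a redrawn split can carry the line's own difference from Col. In the other 9 lines limma-trend gave 0 such genes, as edgeR did, so all 100 splits gave as many and say nothing about chance. The highest other split gave 165 in GABI_513E07, 9 in SAIL_1207_H04, 37 in SALK_012253 and 1 in SALK_035980. It gave 560 in SALK_070847C, 133 in SALK_085964C, 1 in SALK_094437C, 5 in SALK_100002 and 124 in SALK_146141. What the splits with over 100 genes reflect, as in GABI_513E07, SALK_070847C, SALK_085964C and SALK_146141, was not tested either.

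For the nitrate response chance can be excluded, in Col among 35 splits (3483 genes by limma-trend, highest other 0) and over all lines among 100 (12734, highest other 1). Among the lines it can be excluded for GABI_513E07 (165, highest other 56), GABI_699B09 (2134, highest other 804), SAIL_1207_H04 (15, highest other 1), SALK_012253 (18, highest other 26) and SALK_015182 (15, highest other 23). The same is true of SALK_035980 (13, highest other 251), SALK_070847C (37, highest other 151), SALK_085964C (11, highest other 101), SALK_094437C (7, highest other 651), SALK_100002 (10, highest other 167) and SALK_146141 (28, highest other 125). It could not be excluded for GABI_868_E02 (11, highest other 33). These splits were drawn without regard to strip, and with 12 lines tested the exclusion is weak where another split called more genes than the real one. Splits that call several times the real count, as in the last 6 SALK lines, point to a structure of the samples. Of the splits with the highest counts, those of SALK_012253 and SALK_070847C matched replicates 1 and 2 against replicates 3 and 4 in 14 of 16 libraries, where the average over splits was 9.58 and 9.39. In the other 10 lines the highest splits matched in 8 to 12, 10 of them in SALK_094437C. With a replicate block edgeR called 176 genes in SALK_012253 and 180 in SALK_070847C.

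Organelle genes, left out of the comparisons, gave a signal in run 1 and none in run 2: 68 of them had over 200 counts in run 1 and 0 in run 2, while no nuclear gene did. They made up between 0.251% and 1.34% of the run 1 counts of a library, with a median of 0.456%, in all libraries. Run 1 holds organelle counts that run 2 lacks for every library, and the reason was not tested.

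In GABI_699B09, genes that differed from Col lay in blocks of neighbouring genes: 1330 of 4702 genes inside 6 blocks were called (28.3%, 477 higher and 853 lower) and 955 of 14962 outside them (6.38%, 420 higher and 535 lower), and the highest window of 100 genes held 54% where 1000 shuffles of the gene order gave at most 28%. The count fell no lower than 1559 when a replicate was left out, which argues against a single aberrant library, and blocks on 3 chromosomes argue against linkage to a single insertion site. The line's median total of 9.45e+06 lies above the 7.11e+06 to 9.05e+06 of the other lines, which met the depth criterion first set down, and a thinning test chosen after that was seen argues against depth: with the line thinned to the lowest of those medians, 1256 of the 1330 genes called in the blocks were called again, and 2197 genes in all. Segments of another accession's genome are a candidate explanation that stays open: with blocks fixed on odd-numbered genes, even-numbered genes were called 4.18 times as often inside as outside (28.4% against 6.79%), and 17 of the 20 genes under 1 CPM in this line's libraries and over 2 CPM in all others lay in blocks, as did 58.2% of all called genes. No sequence was at hand to test it, nor to tell lost transcripts from tags that no longer match the reference, and a different plant line under this name could look the same.

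The level of MRD1 may follow the parental stock from which a collection was made. Of all 715 choices of 4 of the 13 lines, 1, the GABI and SAIL lines, had a gene whose libraries did not overlap with the rest, but that choice was made because of MRD1 and no other gene separated these libraries fully, so the parental stock stays open. In all 13 strips every GABI or SAIL library lay above every Col or SALK library, which argues against strips as the cause. The insertions as a cause, and variants of the MRD1 region between stocks, stay open and were not tested.

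Col stood apart from the 12 insertion lines, a contrast chosen after the data were seen: edgeR called 386 genes, 281 higher and 105 lower in Col, where the same contrast gave 2924 for GABI_699B09, 445 for GABI_513E07 and between 28 and 158 for each of the other 10 lines. Whichever insertion line was left out of the mean, 212 of them were called, which argues against single lines that pull the mean for these, while for the other 174, not called without some line, it stays open. The largest loss was without GABI_699B09, where 244 of the 386 were called, against 332 to 385 without any other line. With strip as a covariate 1523 genes were called, which argues against strips as the whole cause, and the Col median total of 8.84e+06 lies inside the range of the lines, 7.11e+06 to 9.45e+06, which argues against depth. Chance can be excluded only weakly (160 genes by limma-trend, highest other split 590), since the splits ignore strip and the contrast was picked among 13 lines, a split with 590 points to a structure of the samples, and the count rested on single Col libraries: it was 95 without Col 10 mM replicate 2, 139 without Col 10 mM replicate 3, 620 without Col 10 mM replicate 4, 636 without Col 1 mM replicate 1, 118 without Col 1 mM replicate 2, 242 without Col 1 mM replicate 4 and 49 without replicate 2 of every group. A seed batch of Col apart from that of the lines could give such a pattern, stays open and was not tested.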

How the results depend on the processing

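The fits to run 2 alone, with organelle genes kept, without GABI_699B09 and within 3 strips, the leave-outs and single runs for gene lists, and every setting of Col against the 12 lines were chosen after the data were seen. Of 641 counts under an alternative 459 stayed within 1.5 times of the reported count and 182 moved further. Among named genes, 2652 of 2779 values of 187 genes in the nitrate comparisons kept their direction and side of the threshold, 126 kept direction alone and 1 reversed. The values of 81 genes in line comparisons kept both in 1120 of 1213 cases and direction alone in 93, and for 14 more DESeq2 gave no adjusted p. Those of 5 genes in responses kept both in 45 of 72 and direction alone in 27, and the 134 values of 13 genes against the other lines kept both. F3PH over all lines (log2 -0.40) ranged from -0.747 without replicate 2 to 0.0787 without replicate 1, where it reversed (± 0.12 SE, edgeR adjusted p of 0.579), and the cause was not tested. No library had so low a total that the depth alternative left it out. RLE in place of TMM moved no count past 1.5 times.

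The counts that moved past 1.5 times follow by setting. With DESeq2, genes called against Col numbered 67 in GABI_868_E02, 139 in SALK_085964C and 44 in SALK_094437C. Differing responses numbered 4 in GABI_699B09, 4 in GABI_868_E02 and 4 in SALK_015182. With limma-voom, genes called against Col numbered 45 in SALK_035980. Responses to nitrate differed for genes numbering 0 in GABI_868_E02. Without a low-count filter, genes called against Col numbered 34 in SALK_085964C. Genes with a differing response numbered 1 in SALK_015182. With a fit to the compared groups alone, which estimates the spread from fewer libraries, genes called against Col numbered 175 in GABI_513E07, 14 in GABI_868_E02, 17 in SAIL_1207_H04, 28 in SALK_012253, 14 in SALK_015182, 14 in SALK_035980, 46 in SALK_070847C, 10 in SALK_085964C, 8 in SALK_094437C and 27 in SALK_146141. Differing responses numbered 5 in GABI_699B09. With run 1 alone, at lower depth, genes called against Col numbered 86 in GABI_513E07, 1448 in GABI_699B09, 5 in GABI_868_E02, 11 in SAIL_1207_H04, 21 in SALK_012253, 22 in SALK_015182, 14 in SALK_035980, 18 in SALK_070847C, 13 in SALK_085964C, 8 in SALK_094437C and 20 in SALK_146141. Responses to nitrate differed for genes numbering 1 in GABI_699B09, 0 in GABI_868_E02 and 0 in SALK_015182. For nitrate in Col 2171 genes were called, for Col against the 12 lines 220 genes, and for the line effects 7 lists. With run 2 alone, at lower depth, genes called against Col numbered 116 in GABI_513E07, 1474 in GABI_699B09, 17 in GABI_868_E02, 16 in SAIL_1207_H04, 17 in SALK_012253, 16 in SALK_015182, 16 in SALK_035980, 46 in SALK_070847C, 11 in SALK_085964C, 8 in SALK_094437C and 27 in SALK_146141. Genes with a differing response numbered 0 in GABI_699B09, 0 in GABI_868_E02 and 1 in SALK_015182. For Col against the 12 lines 94 genes were called. With the GABI_699B09 libraries left out, 232 genes were called for Col against the 12 lines. Against the other 11 insertion lines in place of Col, genes called numbered 461 in GABI_513E07, 66 in GABI_868_E02, 182 in SAIL_1207_H04, 42 in SALK_012253, 39 in SALK_094437C, 51 in SALK_100002 and 129 in SALK_146141. With strip as a covariate, genes called against Col numbered 611 in GABI_513E07, 400 in GABI_868_E02, 184 in SAIL_1207_H04, 585 in SALK_012253, 252 in SALK_015182, 1040 in SALK_035980, 755 in SALK_070847C, 1425 in SALK_085964C, 247 in SALK_094437C, 83 in SALK_100002 and 77 in SALK_146141. Differing responses numbered 19 in GABI_699B09, 0 in GABI_868_E02, 9 in SALK_015182, 2 in SALK_070847C, 1 in SALK_100002 and 3 in SALK_146141. For nitrate over all lines 7563 genes were called and for Col against the 12 lines 1523. In the 3 strips with both concentrations and fewer libraries, 6955 genes were called for nitrate over all lines. With the 2 libraries of conflicting file names left out, genes called against Col numbered 25 in SALK_085964C. With an estimated correlation camera called 2 lists over all lines, 5 in Col and 0 for the line effects, and fry, which tests the genes of a list without comparing them with others, called 21 over all lines and 1 for the line effects. Where no clause above gives one, the cause was not tested.

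Leaving out 1 Col library, or 1 replicate number in every group, gave line differences of 135 to 373 in GABI_513E07, 8 to 101 in GABI_868_E02, 13 to 32 in SAIL_1207_H04, 8 to 338 in SALK_012253, 11 to 76 in SALK_015182, 15 to 154 in SALK_035980, 13 to 185 in SALK_070847C, 8 to 225 in SALK_085964C, 9 to 39 in SALK_094437C, 7 to 16 in SALK_100002 and 24 to 45 in SALK_146141. Differences in response numbered 0 to 3 in GABI_699B09, 0 to 2 in GABI_868_E02, 0 to 3 in SALK_015182, 0 to 1 in SALK_070847C, 0 to 1 in SALK_085964C and 0 to 2 in SALK_146141, and for Col against the 12 lines 49 to 636 genes were called. The nitrate response gave 3302 to 4493 genes in Col and 11724 to 12016 over all lines, within 1.5 times of the reported counts.

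Calls lost without some replicate number were those of ASN1, BRN2, CHI, F3PH, HAI1, LBD18, MYB12 and PLT2 over all lines, APL, COR47, CYCB1;4, CYP735A2, GLU1, JAZ10, JAZ5, LBD41, LHCB1.2, LHCB1.3, LRX1, PLT1, PP2-A1, SMB, SUC2, SULTR1;1 and VSP1 in Col, GAPA and GAPB in GABI_513E07, AT3G55677 in GABI_868_E02, CBP60G in SAIL_1207_H04, AT5G46295, GSTU20 and MYB9 in SALK_012253, AT3G29410 and AT5G35940 in SALK_015182, ARP9 and AT1G74300 in SALK_035980, AT5G46295, GAPA, LHCA2, LHCB1.3, PSAD1 and PSAL in SALK_070847C, AT3G32040 and AT5G46295 in SALK_094437C, ARP9 and AT5G46295 in SALK_100002, and all 5 differences in response (AT3G48840, AT5G49840, AT5G61590, NAC003 and PHYA). Calls lost with limma-voom were those of BRN2 over all lines, GLU1, LBD41, LHCB1.2, LHCB1.3 and SULTR1;1 in Col, AT4G08593 in GABI_513E07, AT3G55677 in GABI_868_E02, CBP60G in SAIL_1207_H04, AT1G74300 in SALK_035980, AT5G46295 in SALK_070847C and SALK_094437C, and the difference in response of PHYA. With strip as a covariate they were those of BRN2, CHI, CYCB1;4, F3PH, LAC17, LBD18, MYB12, MYB28, RAB18, SMB and SUC2 over all lines, APL, COR47, CYCB1;4 and SUC2 in Col, GAPB in GABI_513E07 and the difference in response of PHYA. The number of libraries limits small changes: in simulated counts 2% of genes with the smallest simulated change were called in Col, with 4 libraries per concentration, and 100% over all lines, with 52. No simulation varied depth, and run 1 alone, at lower depth, gave 2171 genes for nitrate in Col.

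With replicate number as a block term, which the labels do not state to be a pairing, edgeR called 5079 genes for nitrate in Col and 12877 over all lines, and among the counts that moved, genes called against Col numbered 59 in GABI_868_E02, 180 in SALK_070847C and 105 in SALK_085964C. Responses to nitrate differed for genes numbering 4 in SALK_015182. Deviations from the group means of libraries that share a replicate number but not a group correlated by 0.0544 on average, and of those that share a strip by 0.180.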

Other observations

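The values in this part belong to genes chosen after their values were seen, and the tests of them, edgeR quasi-likelihood with Benjamini-Hochberg adjustment against the other 12 lines, were chosen then too. FLC was at 26.6 ± 10.5 CPM (SD, n = 8) in GABI_513E07, between 13 and 45.2 CPM per library, and at 4.27 ± 2.03 CPM in the other 96 libraries, none above 10 CPM (log2 difference 2.68 ± 0.11 SE, adjusted p of 8.00e-37). NAC032 was at 17.5 ± 4.98 CPM in SALK_012253 and at 8.50 ± 2.30 CPM in the other 96 libraries (1.02 ± 0.10 SE, adjusted p of 3.81e-12), with the highest of those 96 at 19.3 CPM. QQS was at 47.4 ± 11.5 CPM in SAIL_1207_H04, at least 36.7 CPM in each library, and at 1.22 ± 0.599 CPM in the other 96 libraries, at most 2.49 CPM (5.42 ± 0.09 SE). ARF9 was at 48.1 ± 21.3 CPM in SAIL_1207_H04 and at 96.9 ± 32.5 CPM in the other 96 libraries (-1.05 ± 0.10 SE).

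Among the 386 genes that set Col apart from the 12 insertion lines, AT3G25150 was at 33.0 ± 11.2 CPM in the 8 Col libraries and at 78.7 ± 17.0 CPM in the 96 others, with line means from 71.5 to 83.6 CPM. ARP9 was at 12.8 ± 2.61 CPM against 7.13 ± 1.53 CPM, NPU at 59.4 ± 11.3 CPM against 45.8 ± 5.32 CPM and TED4 at 220.2 ± 42.0 CPM against 165 ± 24.2 CPM.

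In GABI_699B09, 3 genes were over 2 CPM in all 8 libraries and under 1 CPM in all other 96: AT1G12340 at 16.2 CPM, AT1G19550 at 12.3 CPM and VPS24.2 at 3.40 CPM. All 3 lie in the blocks of called genes, which run from AT1G09280 to AT1G13920, AT1G16220 to AT1G27500 and AT1G71500 to AT1G80980 on chromosome 1, AT3G26744 to AT3G54720 on chromosome 3, and AT5G41663 to AT5G53080 and AT5G58320 to AT5G66670 on chromosome 5.

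For the pair of libraries whose file names carry the other line, the levels of a gene low in each line follow the labels: AT1G76510 was low in all 8 libraries given as SALK_035980, at most 1.84 CPM, and AT5G27550 in all 8 given as SALK_085964C, at most 3.69 CPM, against at least 5.49 CPM for AT5G27550 and 8.43 CPM for AT1G76510 in the other 96.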
